A study of Corynebacterium glutamicum with 3 samples.

How the data were processed

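RNA of *Corynebacterium glutamicum* ATCC 13032 grown with 200 mM 5-aminovalerate (5AVA) or 200 mM NaCl was compared on 3 two-colour arrays. Per the labels, 50 mL cultures started at an optical density of 1.0 and were collected at a density between 15 and 26. Per the labels, the NaCl RNA carried Cy5 and the 5AVA RNA Cy3 on arrays 1 and 3, and the dyes were exchanged on array 2. The labels call the arrays technical replicates. All 3 entered every test.

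Spot intensity values, deposited per array, were measured with ImaGene 5.5 and exported from an array database, per the file headers. They are linear and not normalized, with a flag per spot that was the same in both channels. The authors' deposited sheets hold, per gene and array, a ratio of channel 1 over channel 2, the number of unflagged spots, an SD, a test score and p-values over spots. The deposited series table holds log2 values; the sorted values of each column equal log2 of that array's sheet ratios rounded to 2 decimals, to within 4.98e-05, so its scale is log2 and its direction channel 1 over channel 2. Its column medians were -0.0589, -0.0439 and -0.0439, and its rows name no gene. The authors' other columns, such as the flags and the SD over spots, were used as described. The authors' normalization and software after ImaGene are not given in the sources used here. Against scanner values with plain background subtraction and loess, the authors' log2 ratios differed by a median of 0.0174, 0.0435 and 0.0480 on arrays 1, 2 and 3, and with median centring in place of loess by 0.496, 0.384 and 0.195, so of these 2 the centring was closer to loess.

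Each array had 13824 spots, 12272 of them for 3068 genes (4 spots per gene) and 1552 for controls. Flags took out 29.2%, 18.2% and 41.2% of the gene spots on arrays 1, 2 and 3. With limma 3.58.1 in R 4.3.3, the mean intensity of each spot was corrected with the mean local background by normexp with an offset of 50 (fitted on all spots), and log2 ratios of channel 1 over channel 2 were normalized within each array by loess, with control and flagged spots at weight 0. The unflagged spots of a gene were averaged, and 1896 genes with a value on all 3 arrays were tested with lmFit and eBayes against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The estimated prior for the variance had infinite degrees of freedom, so every gene had the same SE. No array was turned, because channel numbers follow the medium: the channel with a median local background of 7 changed from channel 2 to channel 1 on array 2. Which medium is channel 1 rests on titles and headers and is called likely. A gene was well above background in a channel where its signal exceeded the median of the negative and empty spots by 3 scaled median absolute deviations. The precision is limited by the number of arrays.

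The gene lists were fixed before the data were examined, as were the test, normexp, loess and most alternatives. Lists were tested with camera at a preset correlation of 0.01, over the genes tested, and with an estimated correlation and fry beside it. Names came from the authors' sheets, which give a symbol to 1102 of the 3068 genes. The reference table given (assembly ASM1132v1) numbers genes in another way, and no coordinates were used. Chosen after a first look at the data under several combinations of background, foreground and normalization were the requirement of all 3 arrays (16 genes passed with at least 2), the mean instead of the median local background (20 genes with the median) and the definition of well above background. The text names the members of the list on 5AVA use, the 12 genes with the largest change in each direction among those past the threshold, of the same sign on all arrays and well above background on every array in the brighter medium's channel, filled up with those of smallest unadjusted p where fewer than 12 pass, and from each other list up to 3 members past the threshold with the largest change, or else the 2 with the largest absolute ratio.

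The limma fit was tested on simulated data for the comparison of 5AVA with NaCl over 1896 genes, 200 of them changed. At 2-fold it called 79.5% of these with 8 false calls, and at 4-fold 100% with 8 false calls. Every simulated gene had the same normal SD of 0.453 between independent arrays, the form that the main fit assumes. These rates therefore do not measure the error on the real arrays, where that form may not hold. Known rises of channel 1 were also put into the scanner intensities of 200 genes taken at random. A true 2-fold rise came back as a median of 1.72-fold and a true 4-fold rise as 3.10-fold, so such rises were understated. Falls in channel 1 were not tried. For genes chosen because they passed a threshold, this does not say whether the ratios are understated. Alternatives covered the background, foreground, centring, flags, duplicate spots, dye effect, variance prior, thresholds, the authors' values and each array left out. Figures were drawn with matplotlib 3.10.9.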

Results

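The data were 3 two-colour microarrays of *Corynebacterium glutamicum* ATCC 13032, a soil bacterium used to make amino acids. 5-aminovalerate (5AVA) is a 5-carbon amino acid made from lysine. Cells grew from the start in CGXII minimal medium with 4% glucose and either 200 mM 5AVA or, as the control, 200 mM NaCl, and were collected in mid-exponential growth. Every array held RNA of both cultures, each in its own dye, and the dyes were exchanged on array 2. Each of 3068 genes was printed as 4 spots, and 2345 genes gave at least 1 unflagged spot on array 1, 2705 on array 2 and 1948 on array 3, so that 1896 genes were measured on all 3. One channel was bright on each array, with 100% of the measured genes well above background, and the other was dim, with 50.2%, 29.9% and 35.4% of them well above background on arrays 1, 2 and 3.

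The first comparison asked which transcripts differed in level between cells grown with 5AVA and cells grown with NaCl. Among the 1896 genes measured on all 3 arrays, the gene with the highest ratio was narK (cg1345), a putative nitrate/nitrite permease, at 3.66-fold higher in channel 1 (log2 ratio 1.87 ± 0.26, SE of the limma fit, 3 arrays). Among the next highest was glgC (cg1269), which makes the ADP-glucose used for glycogen synthesis, at 2.81-fold. So were ftn (cg2782), a ferritin-like protein that stores iron, at 2.65-fold, and hemH (cg1734), the ferrochelatase of haem synthesis, at 2.58-fold. Of these, hemH was well above background in channel 2 on only 1 array and glgC on 2. Of central metabolism, pck (cg3169, phosphoenolpyruvate carboxykinase) was 2.10-fold, pfkA (cg1409, 6-phosphofructokinase) 2.07-fold, mdh (cg2613, malate dehydrogenase) 1.96-fold and gpmA (cg0482, phosphoglycerate mutase) 1.83-fold higher in channel 1. Lower in channel 1 were cg1214, a putative cysteine desulfurase, 1.90-fold, and ctpC (cg1329), a putative cadmium-transporting P-type ATPase, 1.91-fold, both well above background in channel 1 on 2 arrays. All of these passed limma's moderated test at a Benjamini-Hochberg adjusted p under 0.05.

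Channel 1 was likely 5AVA and channel 2 NaCl, so that a positive log2 ratio likely means a higher level with 5AVA. The sample titles and the column headers name 5AVA first, the authors' sheets divide channel 1 by channel 2, and the labels call NaCl the control. Against this, the labels' own channel 1 is NaCl, the series' design text puts NaCl first, and so do the names of the scanner files. The dyes do not settle the point. The reverse reading would turn the sign of every ratio given here. The arrays do run the same way: the channel with a local background of 7 (median) was channel 2 on arrays 1 and 3 and channel 1 on array 2, as the exchanged dyes require if channel numbers follow the medium.

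In all, 37 of the 1896 genes passed the test, 30 higher and 7 lower in channel 1, and all 37 had the same sign on the 3 arrays. Of these, 18 reached 2-fold, 17 higher and 1 lower. The other genes with the largest ratios above 0 were cg3343, a putative secreted membrane protein (log2 ratio 1.42), cg2425, a putative permease (1.37), cg0569, a putative cadmium-transporting P-type ATPase (1.30), butA (cg2958), the butanediol dehydrogenase and acetoin reductase (1.30), cg0967, a putative inositol monophosphatase (1.27), cg2957, of unknown function (1.22), cg1373, a putative glyoxalase (1.19), and cg1279, a putative secreted protein (1.19). Of these, cg3343, cg2957 and cg1373 were well above background in channel 2 on only 1 array and cg0569 and butA on 2, so the size and rank of their ratios rest in part on values near background. Their adjusted p ran from 3.87e-05 for cg3343 to 0.000953 for cg1279, and that of narK was 1.89e-09. The arrays were close together for pfkA (log2 ratios 0.92, 1.17 and 1.06 on arrays 1, 2 and 3) and cg0569 (1.57, 1.03 and 1.32). They were far apart for ftn (2.92, 0.20 and 1.10) and for cg2957 (1.90, 0.20 and 1.57).

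On the lower side, 3 genes passed the test and were well above background in channel 2 on every array: ctpC (log2 ratio -0.93), cg1214 (-0.92) and cg0165, a putative membrane protein (-0.90). In channel 1, where the level was lower, only cg0165 was well above background on all 3 arrays. The value of ctpC came mainly from array 3 (-2.41, against -0.16 and -0.22 on arrays 1 and 2), whereas cg1214 lay between -0.70 and -1.07 on the 3 arrays. Another 4 genes passed the test but were well above background on only 1 or 2 arrays in channel 2 and on 2 in channel 1: cg1328, a putative heavy-metal transporting P-type ATPase (-1.01), thiD2 (cg3409), a phosphomethylpyrimidine kinase of thiamine synthesis (-0.93), cg0462, of unknown function (-0.87), and ocd (cg1784), a putative ornithine cyclodeaminase (-0.86). The next genes by p did not pass: cg1227, a putative membrane protein (-0.86), cysK (cg2833), which makes cysteine from O-acetylserine (-0.85; adjusted p = 0.0524 for both), cg3204, a conserved hypothetical protein (-0.82), lipB (cg2422), a lipoyltransferase (-0.81), and psp5 (cg3197), a putative secreted protein (-0.81).

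**Figure D1:**
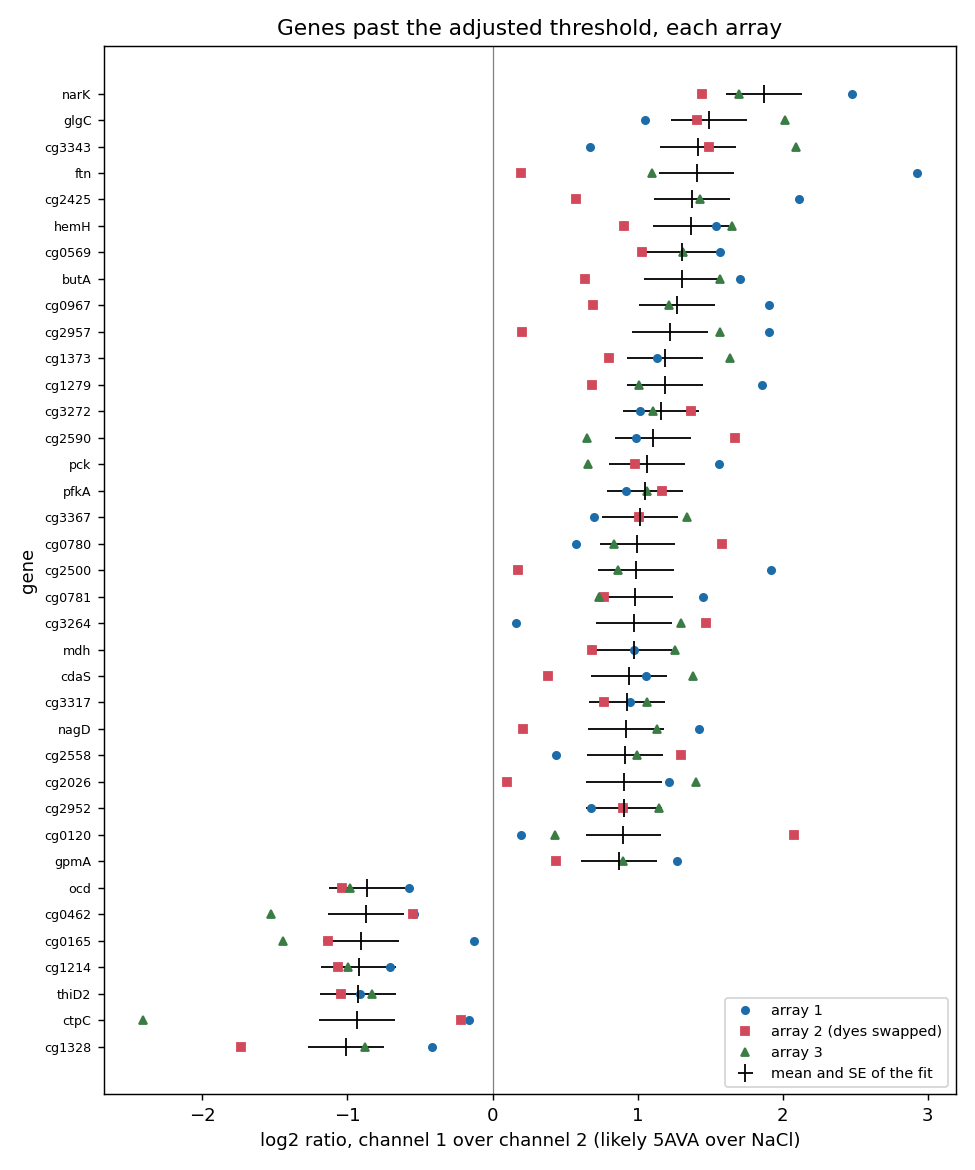
Log2 ratio of channel 1 over channel 2 (likely 5AVA over NaCl) for the 37 genes past the adjusted threshold, with a point per array and a bar for the mean and its SE of 0.26. All 37 genes lie on one side of 0 on the 3 arrays, and ftn and ctpC each have 1 array far from the other two.

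The labels call the 3 arrays technical replicates and name no separate cultures, so these p-values measure only the spread between arrays; if the arrays share 1 pair of RNA extracts, there is 1 replicate per medium and the media themselves were not tested. limma estimated one spread for all genes, an SD of 0.45 between arrays, and with per-gene spreads, with a dye effect in the model or without array 2 it called 0 genes (130, 223 and 225 at an unadjusted p under 0.05, against 208, of which 113 were higher and 95 lower). With the dye effect the median absolute log2 ratio of the 37 was 1.05 (1.00 in the main fit) at a median SE of 0.20, with narK at 1.76 ± 0.23 and cg1214 at -0.96 ± 0.19. Without array 2 it was 1.11 at 0.24. All 37 kept their sign in both fits, but their same sign on all 3 arrays fixed this in advance. Single ratios moved: ftn went from 1.41 to 0.65 without array 1 and to 2.01 without array 2. Without array 2, cg1328 went from -1.01 to -0.65, and the largest fall was from 0.90 to 0.32. These 2 fits had 1 residual degree of freedom in place of 2 and a prior of 4.81 in place of an infinite one. The ratio over its SE was at least as large as in the main fit for 30 of the 37 with the dye effect and for 25 without array 2. Those calls were lost with the fewer degrees of freedom, and equally the main fit made its 37 calls with an infinite prior. Both fits take a gene's own spread from arrays 1 and 3 alone, so they are not 2 separate checks. Arrays 1 and 3 have the same dye orientation, so without array 2 the medium cannot be told apart from a gene-specific dye effect. The counts of 0 do not speak for a dye effect, and the ratios kept without array 2 do not speak against one. With print-tip loess 18 genes passed, 17 higher and 1 lower.

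The genes tied most directly to 5AVA were not seen to differ. gabT (cg0566), the 4-aminobutyrate aminotransferase, had a log2 ratio of -0.41 ± 0.26 (SE, 3 arrays; adjusted p = 0.629), with -0.59, -0.20 and -0.45 on arrays 1, 2 and 3. The lysine exporter gene lysE (cg1424) stood at 0.01 (adjusted p = 0.991) and its regulator lysG (cg1425) at 0.07 (adjusted p = 0.959), both with mixed signs. In channel 1, gabT and lysE were well above background on 2 arrays. In channel 2, gabT was so on 2 arrays and lysE on only 1. The succinate-semialdehyde dehydrogenase genes gabD1 (cg3004) and gabD2 (cg0567) and the permease gene cg0568 lacked unflagged spots on 1 or 2 of the arrays and were not tested. gabD2 read -0.24 and -0.38 on arrays 1 and 2, gabD1 0.09 on array 1 and cg0568 -1.16 on array 2.

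The second comparison asked whether whole groups of genes shifted, for 22 lists. Glycolysis and sugar uptake by the phosphotransferase system (PTS) was called higher in channel 1 only by camera with its preset correlation. In it, 12 of its 13 members had positive ratios, pfkA (1.05) and gpmA (0.87) passed the test and 11 members did not, 3 passed when adjusted over the list alone, and the median log2 ratio was 0.35 (limma's camera at a preset correlation of 0.01 between genes, adjusted p = 0.000415). It did not pass with an estimated correlation (adjusted p = 0.933) or with fry (0.509). Its mean was 0.54, 0.32 and 0.39 on arrays 1, 2 and 3, but single members were less even. On arrays 1, 2 and 3, fda read 1.63, 0.30 and 0.11, gap 1.65, -0.17 and 0.17, and eno 1.10, -0.0095 and 0.16. In contrast, ptsG read -0.55, 0.56 and 1.03, and pfkA was even at 0.92, 1.17 and 1.06. Branched-chain amino acid synthesis and export was called lower only by camera with its preset correlation. In it, all 8 members measured on all 3 arrays had negative ratios, with ilvD (cg1432, -0.65) and leuC (cg1487, -0.64) farthest from 0, 0 passed singly or when adjusted over the list alone, and the median was -0.41 (camera, adjusted p = 0.00437). It did not pass with an estimated correlation (adjusted p = 0.933), with fry (0.726), or with camera without array 2 (0.164). Its mean was -0.18, -0.70 and -0.42 on the 3 arrays, lowest on array 2, where channel 1 was dim. Of its members, ilvD and leuC were well above background in channel 2 on only 1 array and in channel 1 on 2. With an estimated correlation or fry, 0 of the 22 lists passed.

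**Figure D2:**
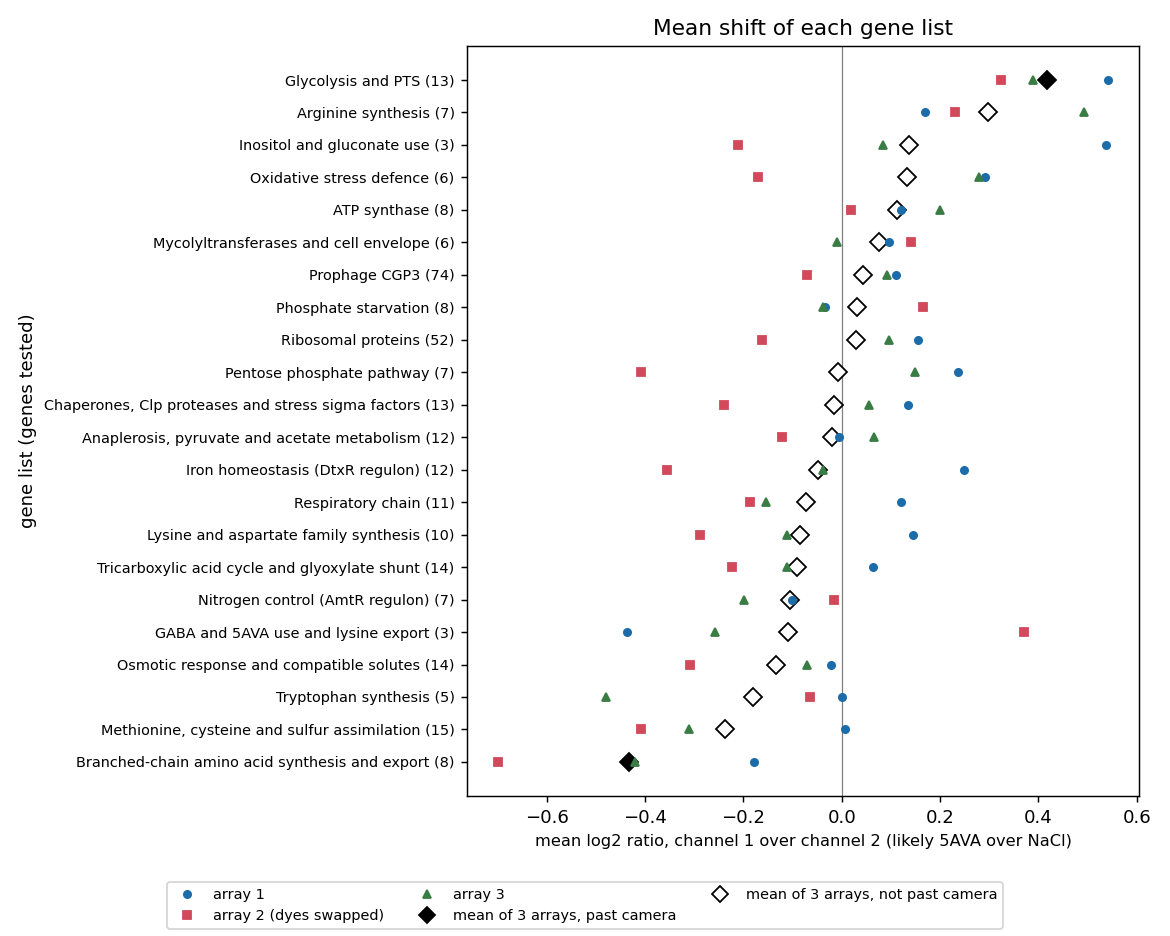
Mean log2 ratio of channel 1 over channel 2 (likely 5AVA over NaCl) of each of the 22 gene lists, with the number of genes tested in parentheses, a coloured point per array and a diamond for the mean over the 3 arrays, filled where camera's adjusted p was under 0.05. Glycolysis and PTS (mean 0.42) and branched-chain amino acid synthesis (mean -0.43) have filled diamonds.

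The other amino acid lists did not pass. Methionine, cysteine and sulfur assimilation had a median of -0.16 over 15 genes (adjusted p = 0.0707), with cysK (-0.85) and cysX (cg3117, a ferredoxin-like protein, -0.66) farthest from 0 and 1 gene lower when adjusted over the list alone. The list passed without background correction (adjusted p = 0.0303) and without array 1 (0.0159), but in the main data not with an estimated correlation (0.933) or fry (0.726). Arginine synthesis had a median of 0.43 over 7 genes, all with positive ratios (adjusted p = 0.122), among them argH (cg1588, 0.49) and argD (cg1583, 0.46). Lysine and aspartate family synthesis had a median of -0.01 over 10 genes (adjusted p = 0.766), where lysC (cg0306), the aspartate kinase that opens the pathway, stood at -0.75 and was lower when adjusted over the list alone (1 gene), and hom (cg1337, homoserine dehydrogenase) stood at -0.61. Tryptophan synthesis had a median of -0.21 over 5 genes (adjusted p = 0.766), with trpCF (cg3362) at -0.40 and trpE (cg3359) at -0.31. Of these named members, argH, argD, lysC, hom, trpCF and trpE were well above background in channel 2 on only 1 array. For the list of 4-aminobutyrate and 5AVA use and lysine export, the median over 3 genes was 0.01, the mean -0.11 and the direction of the test downward (adjusted p = 0.775).

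In the rest of carbon and energy metabolism, single genes passed while their lists did not. The tricarboxylic acid cycle and glyoxylate shunt had a median of -0.13 over 14 genes (adjusted p = 0.766), and only mdh (0.97) passed. Anaplerosis, pyruvate and acetate metabolism had a median of -0.06 over 12 genes (adjusted p = 0.909), with pck (1.07) past the test and 11 members not. The pentose phosphate pathway had a median of -0.02 over 7 genes (adjusted p = 0.956), with opcA (cg1779) at -0.48 and rpi (cg2658) at 0.30. The respiratory chain had a median of -0.04 over 11 genes (adjusted p = 0.766), with qcrC (cg2405, cytochrome c1) at -0.59 and cydB (cg1300) at -0.30, and ATP synthase one of 0.09 over 8 genes (adjusted p = 0.766), with atpG (cg1367) at 0.42 and atpF (cg1364) at 0.32. Inositol and gluconate use had a median of 0.11 over 3 genes (adjusted p = 0.766), with iolG (cg0204) at 0.28 and iolH (cg0205) at 0.11. Of the genes named in this paragraph, opcA, rpi, qcrC and cydB were well above background in channel 2 on only 1 array.

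The lists of nutrient and stress responses gave 1 call, ftn. Iron homeostasis had a median of -0.18 over 12 genes (adjusted p = 0.775), with 8 ratios below 0 while ftn was at 1.41, and adjusted over the list alone 1 gene was higher and 2 were lower. Osmotic response and compatible solutes, which bears on the NaCl in the control medium, had a median of -0.15 over 14 genes (adjusted p = 0.698). Its transporter genes proP (cg3395) and ectP (cg2539) stood at -0.74 and -0.63, and proP was well above background in channel 2 on only 1 array. Nitrogen control had a median of -0.18 over 7 measured of 22 genes (adjusted p = 0.766), with glnK (cg2260, the PII protein) at -0.62 and glnA (cg2429, glutamine synthetase) at -0.39. Phosphate starvation had a median of 0.09 over 8 genes (adjusted p = 0.909), with ugpC (cg1571) at 0.35 and pstA (cg2844) at -0.27. Chaperones, Clp proteases and stress sigma factors had a median of -0.06 over 13 genes (adjusted p = 0.909), with groES (cg0690) at -0.47 and groEL (cg3011) at -0.37. Oxidative stress defence had a median of 0.05 over 6 genes (adjusted p = 0.766), where the regulator gene oxyR (cg2109, 0.77) was higher when adjusted over the list alone and the catalase gene katA (cg0310) stood at 0.15.

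Of the remaining lists, ribosomal proteins had a median of 0.02 over 52 genes (adjusted p = 0.775), with rplO (cg0634) at 0.78 and rplR (cg0630) at 0.77, both below 0 on array 1. Prophage CGP3 had a median of 0.03 over 74 genes (adjusted p = 0.766), and cg2026, a hypothetical protein, passed the test (0.91). Mycolyltransferases and cell envelope had a median of 0.12 over 6 genes (adjusted p = 0.775), with cmt2 (cg3186) at -0.31 and cg2361, the antigen 84 homolog, at 0.28.

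The third comparison asked how far the arrays gave the same genes. Across the 1896 genes, which are not independent replicates, the log2 ratios of arrays 1 and 3 had a Pearson correlation of 0.36 (95% bootstrap interval over genes 0.31 to 0.40), those of arrays 2 and 3 one of 0.19 (0.14 to 0.23) and those of arrays 1 and 2 one of 0.0049 (-0.045 to 0.053). The same sign on all 3 arrays was seen for 584 genes (30.8%), narK, glgC, pfkA, pck and hemH among them. For 3 independent arrays the share would be 25%. The correlation of arrays 1 and 3 alone raises it, so the 30.8% does not show that array 2 goes with the other arrays. Over the 544 genes well above background in both channels on every array, narK, ftn and pck included, the correlations were 0.33, 0.25 and -0.025 in the same order.

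**Figure D3:**
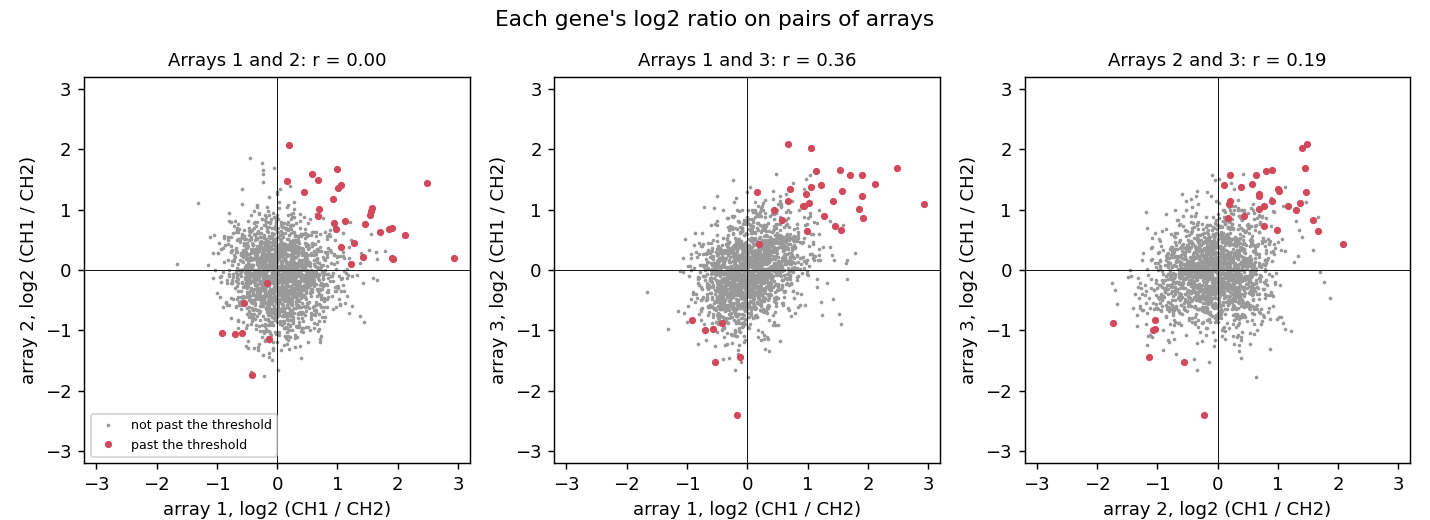
Log2 ratio of channel 1 over channel 2 of each of the 1896 genes on arrays 1 and 2 (left), 1 and 3 (middle) and 2 and 3 (right), with the genes past the adjusted threshold in red. The cloud is tilted for arrays 1 and 3 (r = 0.36) and round for arrays 1 and 2.

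In the authors' deposited sheets, which hold a test over the spots of each array, 215 genes on array 1, 242 on array 2 and 107 on array 3 met a rule of more than 2 spots, unadjusted p of at most 0.05 and at least a 2-fold change. At the authors' adjusted p under 0.05, with no rule on fold or spots, the counts were 533, 76 and 30. Per the authors' deposited table, the rule was met on all 3 arrays by 5 genes, all higher in channel 1: narK, glgC, cg0569, pfkA and cg3272, a putative membrane protein (the last named here after its values were seen). Per the authors' deposited table, it was met in one direction on at least 2 arrays by 39 genes, 30 higher and 9 lower, and 22 of the 39 also passed limma's test. Genes higher on both arrays numbered 21 for arrays 1 and 3 (5.00 expected of independent lists; Fisher's exact test, two-sided, adjusted p = 3.42e-08 over 12 tests), 13 for arrays 2 and 3 (1.77 expected; adjusted p = 3.42e-08) and 6 for arrays 1 and 2 (6.46 expected; adjusted p = 1). Genes lower on both numbered 0, 7 and 2 for the same pairs (0.739, 1.71 and 2.57 expected; exact adjusted p = 1, 0.00479 and 1).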

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

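The arrays carry control reporters that no comparison used, each printed as 16 spots except the positive control. Some were brighter than all but 2.5% of the empty spots in both channels on all 3 arrays. Among 7 reporters each of butA, gap (cg1791), rplL (cg0573) and rplQ (cg0656), whose names end in numbers from 70 to 100, this was so for 1 of butA, 6 of gap, 2 of rplL and 3 of rplQ. The butA reporter numbered 100 had a mean log2 ratio of 1.30 ± 0.45 (SD over 3 arrays), beside 1.30 for the 4 gene spots of butA. For gap, a glycolytic gene, the reporter numbered 100 had 0.57 ± 0.96 and the gene spots 0.55. These close means hide opposite signs on arrays 2 and 3. The gap reporter read 1.47, 0.69 and -0.44 on arrays 1, 2 and 3, and the gene spots 1.65, -0.17 and 0.17. What set them apart was not tested. The rplL and rplQ reporters numbered 100, of ribosomal proteins, had -0.02 and -0.22, beside -0.20 and -0.14 for the gene spots.

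Of the 10 negative control reporters, 2 were brighter than the empty spots in both channels on all 3 arrays, as were 2 of the 12 reporters for calibration. The 1 positive control reporter did not reach this on all 3 arrays.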

How the results depend on the processing

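The count of 37 genes (30 higher, 7 lower in channel 1) depended on several choices, and most causes were not tested. It fell to 12 (12 and 0) without background correction, 18 (17 and 1) with print-tip loess, 4 (4 and 0) with the median of foreground pixels, 18 (17 and 1) with a 2-fold minimum beside adjusted or unadjusted p, and 4 (4 and 0) where 2-fold on all 3 arrays was asked with no test. limma called 0 of 3068 genes with flagged spots kept (228 at an unadjusted p under 0.05) and 0 with a dye effect in the model (223). Median centring called 30 genes (27 and 3) and scale normalization 28 (25 and 3). Leaving out each array gave 0 to 25 genes, 0 to 17 higher and 0 to 8 lower: 25 without array 1, 0 without array 2 (225 unadjusted) and 2 without array 3. Of the 37, 17, 0 and 2 passed again, and 0 passed in every leave-one-out. None took another sign, which their same sign on all 3 arrays fixed in advance. Plain subtraction gave 38 genes (26 shared), separate spots 42 (30 shared), a variance trend 46 (37 shared), the authors' series values 32 and their sheets 26 (23 shared).

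Chosen after seeing the data, genes on at least 2 arrays gave 16 (14 and 2), the median of background pixels 20 (19 and 1), no shared spread 0 (130 unadjusted), array 2 turned 0 (128), and only genes well above background in both channels 15 of 544 (13 and 2). narK passed in 18 of 23 settings, cg0569 and glgC in 16 of 22. A filter on dim genes removed none and says nothing.

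Of 1405 values of 63 named genes under alternatives, 1105 kept their side of the threshold, 285 lost the threshold and 13 gained it. The other 2 reversed: the log2 ratio of ctpC to 0.0059 with the median of foreground pixels and cg1328 to 0.15 with array 2 turned. Reversals were counted only for genes past the threshold in the main or the alternative fit. The 1105 therefore include changes of sign in genes that passed in neither, such as lysE without array 2.

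Of the 22 gene lists, 2 passed camera. With an estimated correlation 0 passed and with fry 0, and leaving out each array gave 1 to 3; the branched-chain list lost the threshold without array 2 (adjusted p = 0.164). The sulfur list gained it without background correction (0.0303) and without array 1 (0.0159). The series values name no gene, so the authors' sheets took their place for lists and gave 2. Under median centring, no background correction and the authors' values, the correlation lay between 0.28 and 0.41 for arrays 1 and 3, 0.13 and 0.21 for arrays 2 and 3, and -0.0042 and 0.044 for arrays 1 and 2. What signal over background limits is the dim channel, where 29.9% to 50.2% of measured genes were well above it. The main fit is already paired, since each array's ratio compares its own 2 media.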

Other observations

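The genes in this paragraph were chosen after their values were seen. Next to narK lie the nitrate reductase genes narG, narH, narJ and narI. Their log2 ratios were -0.00, 0.25, -0.27 and 0.30 (channel 1 over channel 2, likely 5AVA over NaCl), none past the test, against 1.87 for narK. The arrays disagreed for narH (1.43, -0.86 and 0.17 on arrays 1, 2 and 3) and narI (1.17, -0.43 and 0.17). The signs were also mixed for narG, while narJ was below 0 on each array. cg0569, at 1.30, follows the 4-aminobutyrate genes gabT, gabD2 and cg0568 in locus order, and gabT stood at -0.41. Next to glgC, the gene glgA stood at -0.24. Among adjacent genes that passed together were butA and cg2957 (1.30 and 1.22), cg0780 and cg0781, both membrane proteins (1.00 and 0.98), and the P-type ATPase genes cg1328 and ctpC (-1.01 and -0.93).

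The tests of dye effect, spot noise, scanner floor and sign patterns below were chosen after the result was seen. Arrays 1 and 3, of the same dye orientation, correlated more closely (0.36) than either did with array 2. A gene-specific dye effect larger than the effect of the medium would put array 2's correlations below 0, but their mean was 0.0959 (bootstrap interval 0.0528 to 0.135). This rests on arrays 2 and 3 (0.19, 0.14 to 0.23), since arrays 1 and 2 had 0.0049 (-0.045 to 0.053), or -0.025 over the 544 genes well above background in both channels, and do not decide. With array 2 turned, 2 genes passed in place of 37 where one pooled SE was used for all genes, the form of the main fit (131 against 208 at an unadjusted p under 0.05). That count draws on the same agreement between arrays as the correlations, so it is not a separate check. If more spot noise on array 2 were the cause, the gap would vanish on dividing each correlation by the highest that the spots allow. A gap of 0.299 was left (0.221 to 0.351). In the test first written, the first and last 2 spots of a gene correlated at 0.845, 0.517 and 0.573 on arrays 1, 2 and 3. Array 2 was thus well below array 1 but only slightly below array 3 (difference -0.0552). A smaller dye effect stays open: the covariance was 0.0850 for arrays 1 and 3, and the 2 pairs of opposite orientation differed from each other (0.0484 for arrays 2 and 3, 0.00118 for arrays 1 and 2). No biological explanation was tested.

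More of the called genes were higher than lower in channel 1 (30 against 7), while the 208 genes at an unadjusted p under 0.05 were split 113 to 95. What set that more even split was not tested. If the dim channel near the scanner floor were the whole cause, the brightest genes would show no excess, but of the 9 called (8 of them well above background in both channels) among the 308 brightest by the mean of both channels, of which 95% were well above background in both, 100% were higher (exact binomial interval 66.4% to 100%, treating genes as independent). A wider set of 544 gave 89.5% of 19, but 7 of these 19 were near background in a channel on some array. The share among genes well above background in both channels is not used, because the ratio itself helps decide which genes those are. The skewness of the ratios on array 2, the test first written for the floor, was 0.0552 (-0.0866 to 0.197) and left it open. Other values go with the floor: the skewness was 0.662 (0.422 to 0.918) on array 1 and 0.140 (-0.0349 to 0.292) on array 3, and genes at 2-fold were 62 higher and 9 lower on array 1 and 53 and 44 on array 3, where channel 2 was dim, but 35 and 65 on array 2, where channel 1 was dim. The floor as a part of the excess stays open. The loess centring was argued against too, since with median centring 90% of calls were higher. A difference between the media stays open as untested, since 1 of the 4 sign patterns of the 3 arrays, the labelled one, called 37 genes with one SE for all and the highest of the others 2 (208 against 131 at an unadjusted p under 0.05), and 4 patterns are too few for a share under 0.05.

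A hypothesis written before its test was that neighbouring genes share a signal of the medium. The correlation of a gene on array 2 with its neighbour (at most 3 locus numbers away, 1676 pairs) on arrays 1 and 3 averaged 0.0223, within the range of 1000 shuffled gene orders (-0.0288 to 0.0271), and print-tip loess gave 0.0241 (-0.0285 to 0.0281). With loess the mean joined 0.0459 for arrays 2 and 3 with -0.00136 for arrays 1 and 2, and with print-tip loess 0.0364 with 0.0118. Even the same gene on array 2 and on arrays 1 and 3 correlated at a mean of only 0.0959. A weak signal between neighbours could therefore be missed. Such a signal was not detected in the mean, and this does not exclude one.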
